A study of Mus musculus with 7 samples.

How the data were processed

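Gene expression was measured in wound-edge skin of C57BL/6 mice on day 5 after wounding, in 3 MFG-E8 WT animals (2, 3 and 4) and 4 MFG-E8 KO animals (8, 10, 11 and 12), with 1 array per animal and no pooling. Per the labels, total RNA was taken with the miRVana kit, labelled with biotin and hybridised to 1-colour Affymetrix mouse arrays. The animal numbers of the groups differ and the labels name no litter, batch or day of processing, so the groups were compared unpaired and without covariates.

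The deposited values were log2 values from GCRMA, per the submitters' processing notes, which give no version, chip definition or further step. The log base is not stated and was taken as 2, the scale GCRMA itself returns. One value per probe set had been subtracted from all arrays by the submitters: the table holds positive and negative values around 0, and in 72.5% of probe sets a neighbouring middle pair of the 7 values was mirrored around 0 to within a tolerance of 1e-06. Such a pair arises when the median over an even number of arrays is subtracted, so at least 1 array outside the present 7 went into the baseline. The subtracted values are unknown and the table carries no expression levels; the constant cancels in every difference between KO and WT, whose direction is therefore known. Array medians were -0.0042, 0.0119 and -0.0004 for WT animals 2, 3 and 4, and 0.0013, -0.0033, 0.0121 and 0.0069 for KO animals 8, 10, 11 and 12. The number of arrays limits the precision.

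Of 45101 probe sets, 64 controls were left out and 45037 were tested. In the annotation, 34945 of these carry 1 gene symbol, 932 carry several and 9160 carry none; 34737 were matched by Entrez ID to the mouse RefSeq table of assembly GRCm38.p6, with 0 symbols to update. This table gave only names, chromosomes and the order of genes. A filter on the mean level had been planned for tables with levels; since means carry none here, all probe sets were tested, as the plan provided. A coarse level was recovered from the rounding steps of the stored values, which put 19.1% of probe sets between 2 and 4, 53.3% between 4 and 8, and 27.6% at 8 or above on the log2 scale; of simulated probe sets, 95.9% got the right band. The planned choice of 1 probe set per gene by the highest mean was not possible, and the gene value was instead the mean over the gene's probe sets with 1 symbol in its highest recovered band, for 18193 genes.

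Differences (KO minus WT) and their standard errors (SE) came from limma 3.58.1 (lmFit and eBayes) in R 4.3.3, with Benjamini-Hochberg adjustment over the 45037 probe sets and a threshold of 0.05. Mfge8 and list means were also compared by the exact two-sided permutation test over the 35 splits of 7 arrays into 3 and 4, with the p taken as the smaller one-sided share doubled, for which the smallest possible value is 0.0571. Lists were tested with camera at its preset inter-gene correlation of 0.01, adjusted over 29 lists; camera with an estimated correlation and fry were run beside it. The PValue of fry tests whether a list's genes move, on balance, one way, and its Mixed value whether they change in either direction; neither compares the list with other genes. Chromosomes were compared by two-sided Fisher's exact tests. The endothelial list mean was also fitted with the skeletal muscle list mean as a covariate, a test added after seeing the data. Tables were read with Python 3.11.15, pandas 2.3.3 and numpy 2.4.6, and plots drawn with matplotlib 3.10.9.

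The comparison, its tests and thresholds, the 32 gene lists (29 counted and 3 as checks), the rule for named genes and most alternatives were fixed before the data were examined. The rule names Mfge8; the up to 12 genes with the largest difference per direction among probe sets with 1 symbol, adjusted p under 0.05 and groups that do not overlap, filled up to 8 in a direction with fewer than 5; up to 4 members per list with the smallest p; 16 genes of wound repair and inflammation whatever their values; and passing genes among the neighbours of Mfge8. Lists came from textbook knowledge, none was chosen on these samples, and 1 gene (Plaur) is in 2 counted lists. The pipeline was tested on simulated data of the same size: 51% of probe sets changed by log2 1 and 95% of those changed by log2 2 were recovered, and 5.8% of calls were unchanged probe sets. An endothelial list shifted by -0.3 was called and 0 other lists were, but the simulated probe sets varied independently of each other, so this does not give the rate of false list calls in real arrays.

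Alternatives were quantile normalization, subtraction of array medians, eBayes with a trend or robust, array weights, looser thresholds, probe sets without _x_at, _s_at and _a_at names, the mean of all probe sets of a gene, and leaving out each animal in turn. Those added after seeing the data were recovered levels of at least 4 or at least 8, a trend over the level band, the hair gene mean as a covariate, leaving out KO animals 8 and 10 together, and leaving out chromosome 7 genes. The stricter filter and the floor that had been planned could not be run without levels.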

Results

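The series compares day-5 wound-edge skin of mice that carry or lack MFG-E8, a secreted bridging protein that links phosphatidylserine on dying cells to integrins on phagocytes. There were 3 MFG-E8 WT and 4 MFG-E8 KO animals, each on its own array, and all values are centred log2 values, so that differences are given as KO minus WT. The question, per the series title, is which genes differ between the genotypes at the wound edge. The number of arrays limits the precision.

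Mfge8 itself fell by 1.90 on the log2 scale (SE 0.16, 3.74-fold lower, limma adjusted p = 0.00875), from 0.89 ± 0.12 (SD, n = 3) in WT to -1.01 ± 0.28 (SD, n = 4) in KO. Its only probe set of its own (Entrez gene 17304, chromosome 7) lay below every WT animal in all 4 KO animals (exact two-sided permutation p = 0.0571, a doubled one-sided p and the smallest such value that 35 splits allow; by absolute difference 1 of the 35, the real one, was as large). Whether that probe set reads the disrupted part of the gene is not given. The adjusted p was 0.0922 without WT animal 2, 0.0669 without WT animal 3 and 0.059 without KO animal 10, and ranged from 0.00181 to 0.0922 over 17 alternatives.

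Beyond Mfge8, many of the genes that differed lie on chromosome 7. There Hddc3, an HD-domain hydrolase, rose by log2 2.47 (SE 0.10, adjusted p = 0.000159), and Trim12a, a tripartite motif gene of an innate immune family, fell by 3.63 on the log2 scale (SE 0.18, adjusted p = 0.000393). In total 20 of 45037 probe sets passed an adjusted p of 0.05, 4 higher and 16 lower in KO, in 15 genes with a symbol of their own. The other genes that rose were Gprc5b, an orphan G protein-coupled receptor (log2 1.57), Sec23ip, a partner of the COPII coat (log2 1.52), and the uncharacterised 3110040N11Rik (log2 1.27), again all on chromosome 7. Among those that fell were the related Trim30a (log2 -1.66), the cytoskeletal scaffold Iqgap1 (log2 -1.83) and the unconventional myosin Myo7a (log2 -1.55), which lie on the same chromosome. Elsewhere the pseudogene Pisd-ps3 (log2 -2.71), the microtubule-bound ubiquitin ligase Mid1 on chromosome X (log2 -1.89) and the sodium pump regulator Fxyd6 (log2 -1.88) fell. The aggrecan-cleaving protease Adamts4 (log2 -1.27), the cAMP phosphodiesterase Pde4b (log2 -1.10) and the secreted protein gene Lgi2 (log2 -0.99) also fell, with adjusted p from 0.0187 to 0.044. Apart from fits with fewer animals, Pde4b did not pass under eBayes with a trend over the mean centred value (adjusted p = 0.0897), which kept 16 of the 20. Since centred values hold no levels, this was not a trend over intensity, and a trend over the recovered level band kept all 20. Adamts4 did not pass without _x_at, _s_at and _a_at probe sets (0.0575), at a recovered level of at least 8 (0.062) or without chromosome 7 genes (0.075), nor did Trim30a at that level (0.0617).

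Other probe sets of these genes went the same way for Adamts4 (log2 -1.27), Lgi2 (log2 -0.94) and Pde4b (log2 -0.97 and -0.90, with 3 more between 0.050 and 0.15). Those of Hddc3 (log2 -0.076), Gprc5b (log2 -0.12) and Sec23ip (log2 -0.38) did not follow the called one, while the 6 others of Iqgap1 lay between log2 -0.24 and 0.029, and those of Mid1 at log2 -0.19 and 0.0067. Smaller differences were measured by the others of Trim12a (log2 -0.49) and Trim30a (log2 -0.44), and those of Pisd-ps3 ranged from log2 -2.12 to -0.32. Of the 14 passing probe sets with 1 symbol and a known chromosome, 9 were on chromosome 7, which holds 7.03% of such probe sets (Fisher's exact p = 6.01e-08). The 9 include that of the targeted Mfge8 and those of the related Trim12a and Trim30a, and the test treats probe sets as independent. Car6, a secreted carbonic anhydrase (log2 2.24, adjusted p = 0.506), Lrat, which esterifies retinol (log2 1.39, adjusted p = 0.197), Dapl1 (log2 1.29, adjusted p = 0.343) and Micalcl (log2 1.15, adjusted p = 0.134) did not pass, and were the next highest in KO only among probe sets with an unadjusted p under 0.01 and groups that do not overlap. The number of passing probe sets was 7 without WT animal 2, 5 without WT animal 3 and 6 without KO animal 10, and only Hddc3 and Trim12a of the 15 genes passed without each animal in turn. It was 6 without KO animals 8 and 10 together, 13 after quantile normalization and 68 with array weights. The weight was 2.89 for KO animal 10, 0.43 to 0.90 for the other KO animals and 0.77 to 1.53 for WT animals. Counts with array weights, here and below, therefore lean on KO animal 10 in the KO group. Quantile normalization ended 8 of the 20 calls although each of these differences became larger in the same direction. These were a probe set without a symbol of its own (log2 -3.01 before and -4.31 after, adjusted p = 0.121), singled out after its values were seen, Hddc3 (log2 2.98, adjusted p = 0.118), Pisd-ps3 (log2 -3.72, 0.108), Mid1 (log2 -2.31, 0.121), Iqgap1 (log2 -2.18, 0.108), Trim30a (log2 -1.81, 0.0617), Myo7a (log2 -1.62, 0.056) and Lgi2 (log2 -1.02, 0.0617).

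**Figure D1:**
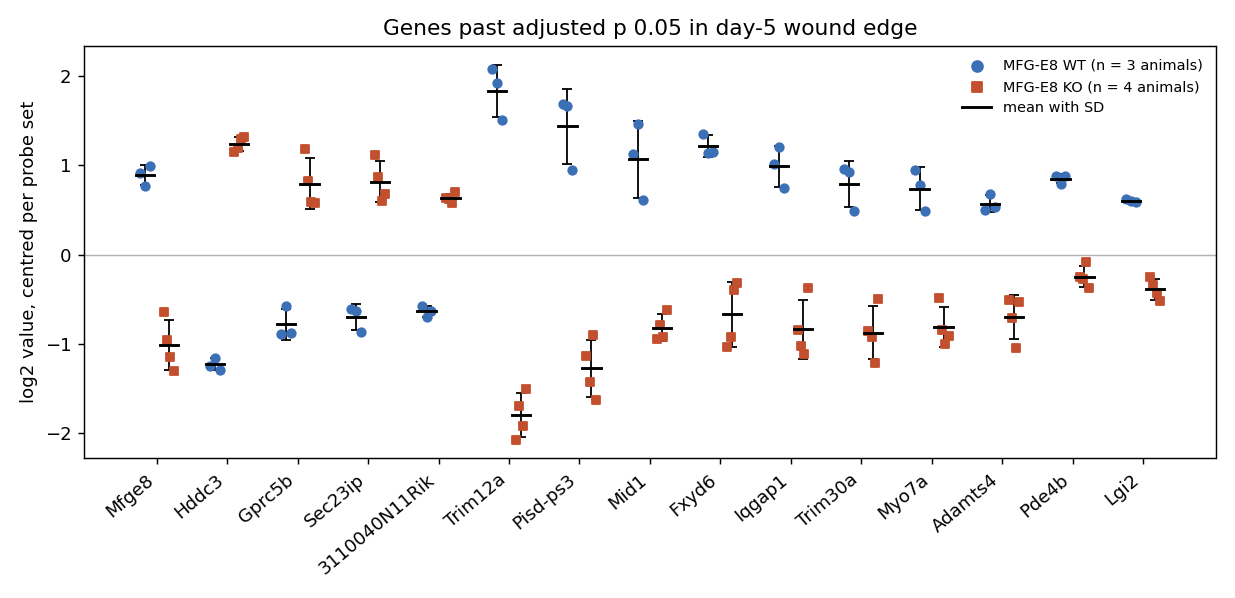
Centred log2 value (vertical axis) of each of the 15 genes past an adjusted p of 0.05, for 3 MFG-E8 WT animals (circles) and 4 MFG-E8 KO animals (squares), with the mean and SD of each group. Mfge8 averages 0.89 in WT and -1.01 in KO. The groups do not overlap for any of the 15, which the rule for named genes required.

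Genes of blood vessels were lower in KO. All 22 measured endothelial markers were lower in KO, by log2 -0.65 on average, and 19 fell when adjusted over the list alone, against 0 over all genes tested. They included Ecscr, an endothelial receptor of cell migration (log2 -0.95), the sialomucin Emcn (log2 -0.95), the transcription factor Sox18 (log2 -1.01), the TGF-beta co-receptor Eng (log2 -0.65) and the junction molecule Pecam1 (log2 -0.80). The list mean was 0.34 ± 0.20 (SD, n = 3) in WT and -0.31 ± 0.19 (SD, n = 4) in KO, without overlap (exact permutation p = 0.0571). Camera gave an adjusted p = 2.35e-20 with its preset correlation of 0.01 and an adjusted p = 0.258 with an estimated correlation, which was 0.50. By fry the unadjusted p was 0.00585 (adjusted p = 0.0848, which did not pass). KO animals 8 and 10, whose hair genes were far above those of the other animals, had the lowest endothelial means (-0.48 and -0.46) and the lowest skeletal muscle means (-1.05 and -0.68), and without both the difference was log2 -0.49 with 4 members that fell. Without WT animal 3, 12 members fell, and with the skeletal muscle mean as a covariate the difference was log2 -0.46 (SE 0.08).

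The angiogenesis list was lower in 27 of 32 genes (mean log2 -0.32, camera adjusted p = 1.37e-08), with an adjusted p = 0.258 with an estimated correlation. Adjusted over the list alone, 4 fell: the sphingosine receptor S1pr1 (log2 -0.84), the apelin receptor Aplnr (log2 -0.95), the VEGF receptor Flt1 (log2 -0.54) and Thbs1, an inhibitor of vessel growth (log2 -0.92). The number was 2 without WT animal 3, 9 without WT animal 4 and 11 with the hair gene mean as a covariate, while with array weights 12 fell and 2 rose. Vegfa itself was at log2 -0.32 (adjusted p = 0.472).

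Inflammatory genes were lower as well. Of 31 cytokine, chemokine and feedback genes 29 were lower in KO (mean log2 -0.44, camera adjusted p = 5.96e-08), with an adjusted p = 0.258 with an estimated correlation. The cytokine Il6 (log2 -1.80), the neutrophil attractant Cxcl5 (log2 -1.41), the acute-phase gene Saa3 (log2 -0.96) and the adhesion molecule Icam1 (log2 -0.47) fell when adjusted over the list alone. That number was 0 without WT animal 4, KO animal 10 or KO animal 12, 2 without WT animal 2 or 3, 10 without KO animal 8, 11 with array weights, 7 with the hair gene mean as a covariate, 0 after quantile normalization, and 2 without chromosome 7 genes, Saa3 being on that chromosome. Tnf (log2 -0.21), Il1b (log2 -0.51), Tgfb1 (log2 -0.60), Il10 (log2 0.18) and Nos2 (log2 -0.18) did not pass.

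Neutrophil markers were lower in 14 of 16 genes (mean log2 -0.54, camera adjusted p = 2.83e-06), with an adjusted p = 0.302 with an estimated correlation. The receptors Csf3r (log2 -1.01) and Cxcr2 (log2 -0.95) fell when adjusted over the list alone, while Trem1 (log2 -0.92) and Mmp9 (log2 -0.85) did not pass. The list mean was log2 -0.29 without WT animal 2, and 4, 5 and 5 members fell without WT animal 3, WT animal 4 and KO animal 8, 3 without KO animals 8 and 10 together, 8 with array weights and 6 with the hair gene mean as a covariate. Monocyte and macrophage markers were lower in all 18 genes (mean log2 -0.39, camera adjusted p = 3.4e-06), with an adjusted p = 0.358 with an estimated correlation. The list means of the groups overlapped (exact permutation p = 0.171). The integrin Itgam (log2 -1.36) and the signalling adaptor Tyrobp (log2 -0.66) fell over the list alone. Both lie on chromosome 7, and without its genes 0 fell and the mean was log2 -0.32 (camera adjusted p = 0.000179). The mean was log2 -0.26 without KO animal 11, 4 members fell without WT animal 4, and 1 fell without WT animal 2, WT animal 3, KO animal 10 or KO animal 11. Genes of alternatively activated macrophages were at a mean of log2 -0.23 (camera adjusted p = 0.00798), with an adjusted p = 0.302 with an estimated correlation, and none of 20 passed. Over the list alone 1 fell without KO animal 10 and 1 with array weights. Without WT animal 2 the mean was log2 -0.14 and the adjusted p = 0.129. Their marker genes Arg1 (log2 -0.37), Mrc1 (log2 -0.31) and Chil3 (log2 -1.03) did not pass.

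Mast cell markers (mean log2 -0.35, camera adjusted p = 0.000109, adjusted p = 0.302 with an estimated correlation) held 1 gene that fell over the list alone, the histamine-forming enzyme Hdc (log2 -0.90). Complement genes (mean log2 -0.23, camera adjusted p = 0.0126, adjusted p = 0.417 with an estimated correlation) held 2, the C5a receptor C5ar1 (log2 -0.89) and properdin, Cfp (log2 -0.59). Dendritic and antigen presentation genes had a mean of log2 -0.19 (camera adjusted p = 0.0423, adjusted p = 0.585 with an estimated correlation) with none passing of 14. Of these 2 fell over the list alone without KO animal 12 and 1 with array weights, and 1 rose without KO animals 8 and 10 together. Mast cell markers were at log2 -0.19 without WT animal 2, and 0 of them fell without WT animal 2, WT animal 3, KO animal 10, KO animal 11 or KO animal 12, against 2 without KO animal 8, 7 of 11 with array weights and 6 with the hair gene mean as a covariate. The complement list lost its call without WT animal 2 (log2 -0.12, adjusted p = 0.289) and KO animal 11 (log2 -0.15, adjusted p = 0.0567), was at log2 -0.38 without WT animal 4, and held 0 that fell without WT animal 2, WT animal 3 or KO animal 10. Among the fits without 1 animal, the dendritic list kept its call only without WT animal 2 (adjusted p = 0.0144) or KO animal 12 (log2 -0.33, adjusted p = 0.000168). Its adjusted p was 0.226 without WT animal 3, 0.0745 without WT animal 4, 0.211 without KO animal 8, 0.0731 without KO animal 10 and 0.116 without KO animal 11.

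Genes of the repair tissue were also lower in KO. Collagens and other matrix genes were lower in 27 of 28 (mean log2 -0.56, camera adjusted p = 2.15e-09), with an adjusted p = 0.377 with an estimated correlation. The basement membrane collagens Col4a1 and Col4a2 (each log2 -0.62) fell when adjusted over the list alone, while the wound matrix gene Tnc (log2 -1.20) and the fibrillar collagens Col1a1 (log2 -0.43) and Col3a1 (log2 -0.35) did not pass. WT animal 4 (list mean -0.33) lay within the range of the KO animals, and without it 23 members fell and the mean was log2 -0.87. Without WT animal 2 it was log2 -0.37. The number that fell was 0 without WT animal 2, WT animal 3, KO animal 8 or KO animal 10, and 1 without KO animal 11. Fibroblast, myofibroblast and pericyte markers were lower in 14 of 16 (mean log2 -0.38, camera adjusted p = 1.98e-05), with an adjusted p = 0.35 with an estimated correlation. Over the list alone the mesenchymal regulators Twist2 (log2 -0.84) and Prrx1 (log2 -0.52), the PDGF receptor Pdgfrb (log2 -0.62) and the surface marker Thy1 (log2 -0.58) fell. None (0) fell without WT animal 2, WT animal 3 or KO animal 10, and without KO animal 11 1 fell and the mean was log2 -0.24.

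Metalloproteinase, plasminogen system and inhibitor genes were lower in 15 of 18 (mean log2 -0.44, camera adjusted p = 1.98e-05), with an adjusted p = 0.302 with an estimated correlation. Adamts4 (log2 -1.27), the inhibitor Timp1 (log2 -1.35) and the surface protease Adam8 (log2 -0.75) fell over the list alone, and 5 did without WT animal 4. Without chromosome 7 genes, among them Adam8, 2 fell. With array weights or the hair gene mean as a covariate 8 fell and 1 rose in either setting, and 1 rose without KO animal 11 or after quantile normalization.

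**Figure D2:**
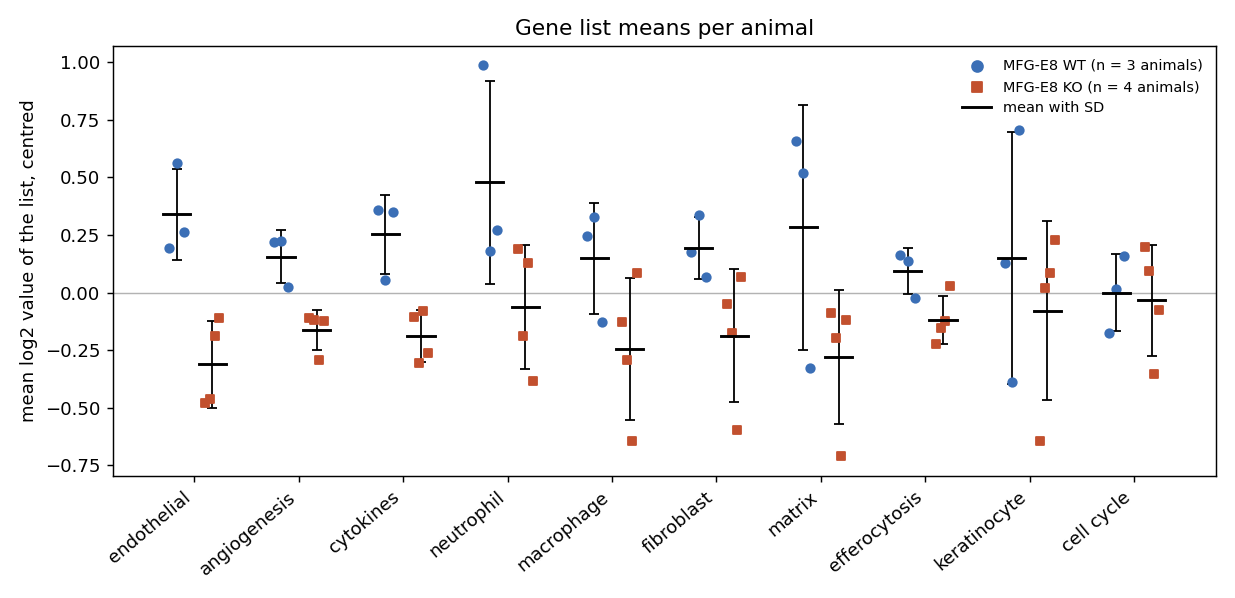
Mean centred log2 value of the members of 10 gene lists (vertical axis) in each of 3 MFG-E8 WT animals (circles) and 4 MFG-E8 KO animals (squares), with the mean and SD of each group. Endothelial means lie from 0.19 to 0.56 in WT and from -0.48 to -0.11 in KO. The groups overlap for the neutrophil, macrophage, matrix, efferocytosis, keratinocyte and cell cycle lists.

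Genes that take part in the clearance of dying cells, the process MFG-E8 serves, were lower by a small mean difference. In the efferocytosis list 27 of 33 genes were lower in KO (mean log2 -0.21, camera adjusted p = 6.74e-05), with an adjusted p = 0.302 with an estimated correlation, and the transglutaminase Tgm2 (log2 -0.76) fell over the list alone. The number was 0 without WT animal 3 and 4 without WT animal 4. The receptors Stab1 (log2 -0.53), Lrp1 (log2 -0.55), Axl (log2 -0.058) and Mertk (log2 -0.0070) and the bridging protein Gas6 (log2 -0.17) did not pass. Apoptosis regulators were at a mean of log2 -0.15 (camera adjusted p = 0.0043, adjusted p = 0.302 with an estimated correlation), where the inhibitor Birc3 (log2 -0.64) fell over the list alone. Of these genes 0 fell without WT animal 2, WT animal 4, KO animal 10, KO animal 11 or KO animal 12. Immediate early and heat shock genes were at log2 -0.21 (camera adjusted p = 0.00183, adjusted p = 0.302 with an estimated correlation), and the transcription factors Fos (log2 -0.80), Fosb (log2 -0.81) and Klf2 (log2 -0.60) fell over the list alone. There 0 fell without WT animal 2, WT animal 3, KO animal 11 or KO animal 12, and 5 without WT animal 4. Hypoxia and glycolysis genes were at log2 -0.19 (camera adjusted p = 0.0126, adjusted p = 0.454 with an estimated correlation) with none passing of 18. Without WT animal 2 the mean was log2 -0.077 and the adjusted p = 0.346, and without WT animal 3 the mean was log2 -0.30.

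Hair follicle keratins and hair genes were the 1 list that passed camera's preset test with higher values in KO. All 23 were higher (mean log2 2.40, camera adjusted p = 3.22e-06), with an adjusted p = 0.5 with an estimated correlation, and none passed when adjusted over the list alone. Examples are the hair keratins Krt33b (log2 3.04), Krt72 (log2 2.53) and Krt81 (log2 2.55) and the follicle transcription factor Foxn1 (log2 0.98). KO animals 8 and 10 had means of 3.93 and 3.96, whereas KO animals 11 and 12 lay at -2.45 and -0.82 and WT animals 2, 3 and 4 at 0.75, -1.69 and -2.82 (exact permutation p = 0.343). Without both animals the mean difference was log2 -0.39 (camera adjusted p = 0.121). It was log2 1.48 without KO animal 8 and 1.47 without KO animal 10, after quantile normalization log2 1.19. The 5 pigment cell genes of the melanocyte and Schwann cell list were highest in these animals, whose list means were 1.47 and 1.05. Of the 10 members 6 were higher and 4 lower in KO. The lower ones included Cdh19 (log2 -0.49) and Mbp, whose probe sets lay from log2 -1.08 to -0.17. The list's difference did not pass (mean log2 0.50, camera adjusted p = 0.435). That mean was log2 0.11 without KO animal 8, 0.25 without KO animal 10, 0.22 without WT animal 4, 0.76 without WT animal 2 and 0.91 without KO animal 11. Skeletal muscle genes were lower in KO in 22 of 22 (mean log2 -0.53, camera adjusted p = 7.9e-06, adjusted p = 0.481 with an estimated correlation), none past the threshold over the list alone, and were lowest in the same KO animals 8 and 10 (-1.05 and -0.68). Without both the muscle mean was log2 -0.079 (camera adjusted p = 0.344), without KO animal 8 it was log2 -0.32 and without WT animal 3 it was log2 -0.34.

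**Figure D3:**
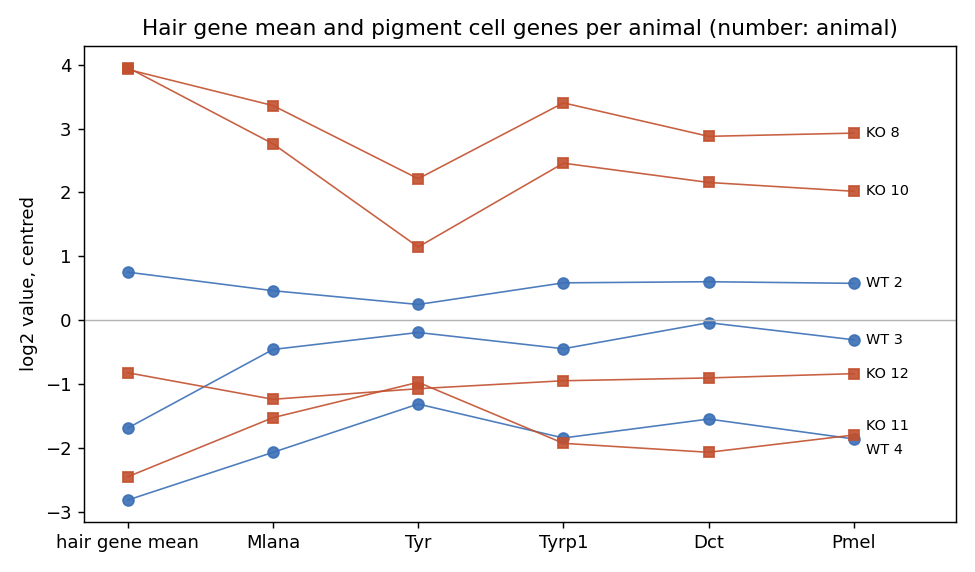
Mean centred log2 value of 23 hair genes and centred log2 values of 5 pigment cell genes (vertical axis) in each of the 7 animals, with 1 line per animal (circles WT, squares KO). KO animals 8 and 10 lie above the other 5 animals for the hair mean and for every pigment gene.

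The remaining lists did not pass. Activated wound-edge keratinocyte genes had a mean of log2 -0.23 (camera adjusted p = 0.263), with the protease inhibitor Slpi at log2 -0.56 and the wound keratin Krt6a at log2 -0.025. Epidermal differentiation genes (log2 -0.036, adjusted p = 0.781), sebaceous gland genes (log2 0.14, adjusted p = 0.113), adipocyte genes (log2 -0.17, adjusted p = 0.28) and cell cycle genes (log2 -0.034, adjusted p = 0.607) did not pass either. T and NK cell markers were at log2 -0.12 (adjusted p = 0.263), with the T cell receptor chains Cd3d at log2 -0.54 and Cd3g at -1.02, and B and plasma cell markers at log2 -0.15 (adjusted p = 0.0973). Without 1 animal the T and NK mean ranged from log2 -0.28 to -0.017 and the sebaceous mean from log2 0.045 to 0.23. Interferon-stimulated genes (mean log2 0.021, median -0.0002, adjusted p = 0.866) and circadian clock genes (log2 0.023, adjusted p = 0.781) averaged close to 0. Erythroid genes had a mean of log2 -0.27 and a median of 0.099 (adjusted p = 0.781), of opposite sign, since the haem synthesis gene Alas2 alone was at log2 -2.32 and fell over the list alone. It did not pass without WT animal 2, WT animal 3, KO animal 8, KO animal 11 or KO animal 12, and the list mean was log2 -0.078 without WT animal 2, -0.51 without WT animal 4 and -0.17 without KO animal 12. Leaving out 1 animal brought some of these lists past the threshold. These were adipocyte (log2 -0.36), cell cycle (log2 -0.12) and sebaceous genes (log2 0.22) without WT animal 2, and keratinocyte genes (log2 -0.50) without WT animal 3. Further ones were, without KO animal 8, epidermal differentiation (log2 0.28), sebaceous (log2 0.23) and cell cycle genes (log2 -0.11), without KO animal 11 B cell markers (log2 -0.21), and without KO animal 12 T cell markers (log2 -0.28) and interferon-stimulated genes (log2 -0.21). The sign of the mean turned without 1 animal for the keratinocyte list (log2 0.050 without WT animal 4), the epidermal list (log2 0.013 without WT animal 2, 0.15 without WT animal 4, 0.0012 without KO animal 10) and the adipocyte list (log2 0.027 without WT animal 3). It also turned for the cell cycle list (log2 0.046 without WT animal 4, 0.072 without KO animal 11), the interferon list (log2 -0.17 without WT animal 4) and the clock list (log2 -0.016 without WT animal 3, -0.033 without KO animal 11, -0.036 without KO animal 12).

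As checks, 40 neighbours of Mfge8 averaged log2 0.00 (exact permutation p = 0.971). Of these, 20 were lower and 20 higher in KO, so the mean cannot show shifts that go both ways. Over the list alone 1 rose, Ngrn (log2 0.54). None (0) rose without WT animal 2, WT animal 3, KO animal 8, KO animal 10 or KO animal 12 or after quantile normalization, while 3 fell without WT animal 4 and 1 without KO animal 11. Sex-specific genes averaged 0.073 (exact permutation p = 0.229) and genes that differ between C57BL/6 substrains -0.097 (exact permutation p = 0.514). The sex list pools Xist with Y-linked genes, which differ between the sexes in opposite directions, so its mean cannot check sex. Single probe sets lay from log2 -0.087 to 0.14 for Xist and from -0.046 to 0.090 for Kdm5d. Those of Uty lay from log2 0.067 to 0.28 and those of Eif2s3y at 0.053 and -0.052 (SE 0.14, recovered level of at least 8). These values argue against a difference of sex between the groups as a whole. The substrain mean covers 3 genes and does not show single ones. Probe sets of Nnt lay from log2 -0.27 to -0.025 and those of Wdfy1 from -0.28 to 0.036, none past the adjusted threshold.

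Over the 29 lists, 18 passed with camera's preset correlation, 17 lower and 1 higher in KO. With an estimated correlation 0 passed (3 at an unadjusted p under 0.05), and by fry 0 passed (8 at an unadjusted p under 0.05, 11 by its Mixed value). The estimates ran from 0.045 (apoptosis) to 0.95 (hair), against the preset 0.01, so list members moved together more than the preset test assumes. The 34 other splits of the 7 animals gave from 2 to 19 lists by camera's preset correlation, with a median of 12. The exact permutation p of the list mean was 0.0571 for the angiogenesis, cytokine, fibroblast, immediate early, apoptosis and alternatively activated macrophage lists. It was 0.114 for the neutrophil, metalloproteinase and efferocytosis lists and 0.171 for the macrophage, mast cell and hypoxia lists. For the matrix and muscle lists it was 0.229, and for the complement and dendritic lists 0.286. Of the 554 genes in these lists 0 passed limma's test over all 18193 genes, where 8 genes did, 2 higher and 6 lower in KO. Without adjustment 111 list genes had an unadjusted p under 0.05, 108 of them lower in KO. Without KO animals 8 and 10 together, 18 lists passed, 14 of them among the first 18, while the hair, muscle, hypoxia (log2 -0.12, adjusted p = 0.125) and dendritic lists (log2 -0.071, adjusted p = 0.633) no longer did. In that setting the epidermal differentiation (log2 0.49, adjusted p = 1.13e-07), cell cycle (log2 -0.21, adjusted p = 4.96e-05), sebaceous (log2 0.32, adjusted p = 0.00267) and clock lists (log2 0.19, adjusted p = 0.0183) passed instead. There 0 matrix and 0 fibroblast genes fell over the list alone, and 2 clock genes rose. Array weights and the hair gene mean as a covariate gave 6 and 14 matrix genes that fell, and 5 and 4 immediate early genes. Array weights also gave 2 T cell markers that fell, and 5 neighbours of Mfge8 that fell with 3 that rose, while the covariate gave 13 endothelial, 1 complement and 0 apoptosis genes. Without chromosome 7 genes 1 complement and 2 immediate early genes fell. Other settings also ended calls. The dendritic list did not pass after quantile normalization (adjusted p = 0.129), with array weights (0.0755), with the hair gene mean as a covariate (0.36), without chromosome 7 genes (0.0546), without _x_at, _s_at and _a_at probe sets (0.0545) or at a recovered level of at least 4 (0.072), nor did the mast cell list without _x_at, _s_at and _a_at probe sets (adjusted p = 0.0512). Without chromosome 7 genes the complement (adjusted p = 0.0608) and hypoxia lists (adjusted p = 0.0725) did not pass. With the hair gene mean as a covariate the muscle list did not pass (log2 -0.15, adjusted p = 0.136), while the epidermal (log2 0.33), sebaceous (log2 0.23) and cell cycle lists (log2 -0.13) did. At a recovered level of at least 8 the apoptosis (adjusted p = 0.113), alternatively activated macrophage (0.115), immediate early (0.057), hypoxia (0.057), complement (0.0838) and dendritic lists (0.167) did not pass. With array weights B cell markers passed (log2 -0.22, adjusted p = 0.0123).

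Without the adjustment, 855 probe sets had p under 0.01 (134 higher and 721 lower in KO; chance gives 450) and 3329 had p under 0.05. Of these 855, 97 differed at least 2-fold, 13 higher and 84 lower, and the number was 236 without WT animal 4 and 163 without KO animals 8 and 10. The groups did not overlap for 3500 probe sets, 7.77% where chance gives 5.71%.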

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

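Apart from the counts over other splits of the animals, the tests of explanations in this part were chosen only after the result was seen. Among 119 results with 4 KO animals, 4 held an animal farther from the rest than Dixon's 95% critical value, while chance gives about 1 in 20 groups, or 5%. The angiogenesis list mean was lowest in KO animal 11 (-0.29, the others -0.12 to -0.11, ratio of gap to range 0.941). The sex-specific list mean was highest in KO animal 8 (0.16, the others -0.02 to -0.01, ratio 0.956). Il10 was highest in KO animal 12 (0.93, the others -0.09 to -0.01, ratio 0.921). Trem1 was lowest in KO animal 12 (-0.72, the others -0.07 to 0.02, ratio 0.869).

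Genes with small p gathered on chromosome 7, where 58 of 1413 genes (4.10%) had p under 0.01 against 2.01% elsewhere (Fisher's exact p = 2.42e-06, 5.08e-05 adjusted over 21 chromosomes, and up to 0.00121 without 1 animal). The targeted Mfge8 is among the 58. Chance cannot be excluded for this excess by splits of the animals, since 6 of the 35 splits gave an odds ratio as high as the real 2.1, the highest other being 2.84. By Fisher's test the excess did not rest on Trim genes and their shared probes alone, since without the 59 Trim genes the exact p was 0.000102. That test treats genes as independent and the splits were not run without Trim genes, so chance stays open there too. A stretch of chromosome 7 around Mfge8 that differs in sequence between the KO and WT mice may account for the excess. It cannot be told apart from an even spread, since the nearer genes held 4.96% and the farther 3.12% (Fisher's exact p = 0.104). Sequence variants under single probe sets stay open as well and cannot be told apart from changes of the transcript. Another probe set was counted if it changed in the same direction and passed limma's threshold of 0.05 without adjustment. Of 10 genes with an adjusted p under 0.10 and another probe set, 4 had one that counted. These were Trim12a, Coro1a, Rab6a and Trim30d, the last 3 named after their values were seen. Of the 6 genes with an adjusted p under 0.05 only 1, Trim12a, had one. Smaller differences in the same direction that fell short of that threshold, such as that of Trim30a (log2 -0.44), were not counted.

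Endothelial markers were lower in all 4 KO animals than in any WT animal (log2 -0.65, SE 0.15), a difference that came with an exact permutation p of 0.0571, a doubled one-sided p, and that by absolute size only 1 of the 35 splits, the real one, reached. As the whole source, KO animals 8 and 10 are argued against by log2 -0.49 (SE 0.15) without them, where the smallest possible exact permutation p is 0.2. A smaller share of all cells other than keratinocytes stays open. The endothelial list lay a further log2 -0.34 (SE 0.09) below the mean of 9 other cell type lists, but it was singled out for its large fall. Neutrophil (log2 -0.54) and muscle lists (log2 -0.53) fell nearly as far, so this test cannot decide. Skeletal muscle means moved with the endothelial means (0.36 per unit, SE 0.08), but with muscle as a covariate the difference was log2 -0.46 (SE 0.08), which argues against less skeletal muscle in the KO samples as the whole source. The choice of the list for its large fall also bears on this fit and that without KO animals 8 and 10, so neither excludes its explanation. Fewer or less active endothelial cells at the wound edge of KO animals may be a hypothesis for the remainder, found on the same 7 animals, which vessel counts in sections of other animals could test. Other differences in the tissue sampled stay open, and with an estimated correlation the list did not pass (adjusted p = 0.258).

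Hair genes were far higher in KO animals 8 and 10 (3.93 and 3.96) than in KO animals 11 and 12 (-2.45 and -0.82) and the WT animals (-2.82 to 0.75), and between the genotypes the exact permutation p was 0.343. A difference in scale between the arrays is argued against as the whole source, since after quantile normalization, which gives all arrays the same scale, these 2 animals were still the highest for 21 of the 23 hair genes. That method lowered their means to 2.05 and 2.08 and the genotype difference from log2 2.40 to 1.19, and left the lower of them 1.17 above the highest WT animal, within the WT SD of 1.55, so an effect of scale on part of the size stays open. The count of 21 was kept among several tests of scale tried after the result was seen, and the verdict depends on which is used. Growing hair follicles with their pigment cells in these 2 samples are a candidate explanation: for 5 of 5 measured pigment cell genes (Mlana, Tyr, Tyrp1, Dct and Pmel, of which the last 4 are named here after their values were seen) these animals were the highest. The place of sampling and the hair cycle stage, which the labels do not give, stay open.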

How the results depend on the processing

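The settings with recovered levels, the hair covariate, the level-band trend, without KO animals 8 and 10 and without chromosome 7 were tests chosen only after the results were seen. The others were planned, and the cause of a change was not tested unless named. Over the settings run, counts of probe sets and lists stayed within 1.5 times of their value, and Mfge8 on its side of the threshold, in 133 cases. Counts moved further in 61, and Mfge8 lost its call in 3, at log2 -1.89, -1.97 and -1.92. A lost or gained call means an adjusted p that crossed the threshold with the same sign, whatever the size of the difference. Named genes kept sign and side in 1522 cases, lost the call in 83, gained one in 9 and had the opposite sign in 30. For lists these numbers were 470, 65, 14 and 28. The 65 include the 18 calls each that an estimated correlation and fry ended, where the means were unchanged. Under each alternative for the values, probe sets or animals, 9 lists passed camera's preset test. With an estimated correlation 0 did (0 lower, 0 higher; 3 at an unadjusted p under 0.05), and by fry 0 did (0 lower, 0 higher; 8 at an unadjusted p under 0.05). Of the 20 passing probe sets, quantile normalization kept 12 and gave 13 (10 lower), with Mertk at 0.040 and Krt6a at 0.038. Array weights, largest for KO animal 10 (2.89), kept 20 and gave 68 (63 lower), with 212 at 2-fold and p under 0.01 (75 higher, 137 lower). Interferon genes were then at -0.018, clock genes at -0.072, cell cycle genes at 0.077 and Krt6a at 0.019. An adjusted p of 0.10 gave 40 (35 lower), and 1.5-fold gave 555 (67 higher, 488 lower), looser by construction. Without _x_at, _s_at and _a_at probe sets, where 12 of the 20 could be tested, there were 11 (7 lower), and 61 at 2-fold (50 lower), with Krt6a at 0.0032 and erythroid genes at 0.090. Mfge8 has no value there, its probe set being of that kind. The mean of all probe sets put Axl at 0.10. At a recovered level of at least 8, with fewer probe sets, 5 passed (2 higher, 3 lower), 34 differed 2-fold (4 higher, 30 lower), 11 lists were lower and clock genes were at -0.020. With the hair covariate, which brings the hair list to 0 by construction, 39 passed (35 lower), 212 differed 2-fold (202 lower) and 2 lists were higher. Values were then -0.012 for interferon genes, -0.28 for Mlana, -0.33 for Tyr, -0.49 for Tyrp1, -0.81 for Dct, -0.50 for Pmel, -0.31 for melanocyte genes, 0.056 for adipocyte genes, 0.16 for Krt6a and 0.33 for epidermal differentiation. Without KO animals 8 and 10, with fewer animals, 6 passed (1 higher, 5 lower), 163 differed 2-fold (151 lower) and 3 lists were higher. Values were then -0.079 for Krt81, -0.10 for Krt72, -0.39 for hair genes, -0.46 for melanocyte genes, -0.69 for Mlana, -0.60 for Tyr, -0.87 for Tyrp1, -1.16 for Dct, -0.79 for Pmel, 0.0065 for keratinocyte genes, 0.061 for Gas6, 0.072 for adipocyte genes, 0.081 for T cell markers, 0.26 for Krt6a and 0.49 for epidermal differentiation. Without chromosome 7 genes 10 passed (0 higher, 10 lower) of the 11 that could be tested, and 8 were higher at 2-fold. Leaving out 1 animal, with fewer animals, gave 5 to 19 passing probe sets (7 without WT animal 2, 5 without WT animal 3, 6 without KO animal 10), 1 to 4 of them higher (2 without WT animal 2, WT animal 4 or KO animal 10, 1 without WT animal 3) and 4 to 17 lower. At 2-fold they gave 91 to 236 (236 without WT animal 4), 9 to 45 higher (31 without WT animal 2, 45 without KO animal 11, 42 without KO animal 12) and 77 to 220 lower. Lists higher in KO numbered 1 to 3 (2 without WT animal 2, 3 without KO animal 8), and Mfge8 ranged from -2.03 to -1.81 with adjusted p up to 0.0922. Ranges of genes that crossed 0 were Axl -0.17 to 0.020, Il10 -0.066 to 0.28, Krt6a -0.20 to 0.19, Mertk -0.24 to 0.12, Nos2 -0.38 to 0.0092, Tnf -0.37 to 0.12. Those of lists were keratinocyte genes -0.50 to 0.05, adipocyte genes -0.36 to 0.027, cell cycle genes -0.12 to 0.072, clock genes -0.036 to 0.083, epidermal differentiation -0.27 to 0.28 and interferon genes -0.21 to 0.17, all on the log2 scale. A stricter filter and a floor were not run, since the table holds no levels, and no filter is what was tested; the number of arrays and the unknown signal over background limit every value.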

Other observations

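The counts over other splits of the animals were planned; the other values in this part were looked at only after the results were seen. For the number of probe sets past an adjusted p of 0.05, which was 20, chance is argued against but not excluded. Of the 35 splits of the 7 animals only 1, the real one, gave as many, and the highest other gave 1. No smaller share is possible with 35 splits. This count does not bear on single probe sets, and only 2 of the 15 named genes passed without each animal in turn. For the 97 probe sets with p under 0.01 and at least a 2-fold difference, chance cannot be excluded, since 7 of the 35 splits gave as many. The highest other gave 395, for WT animals 3 and 4 with KO animals 11 and 12 against WT animal 2 with KO animals 8 and 10, which points to a structure of the samples that follows the hair genes and not the genotype. For the 18 gene lists, chance cannot be excluded either, as 3 of the 35 splits gave as many and the highest other gave 19. The 34 other splits gave at least 2 lists and a median of 12, and 31 of them gave 8 or more.

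KO animals 8 and 10 had correlated values across probe sets (r = 0.70), where the other pairs of animals lay between -0.443 and 0.212; probe sets are not independent replicates. The spread of the values was widest in KO animal 8 (SD 0.406) and narrowest in KO animal 12 (SD 0.214). The difference between the 3' and 5' control probe sets, a sign of RNA degradation, was log2 0.10 for Gapdh (exact permutation p = 0.571), 0.14 for beta-actin (exact permutation p = 0.343) and -0.10 for the transferrin receptor (exact permutation p = 0.4).

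Among 82 genes within 5 Mb of Mfge8, 2 passed an adjusted p of 0.05 in the gene-level fit, 3110040N11Rik and Hddc3, and 3 rose and 0 fell when adjusted over these genes alone by limma. Leaving out 1 animal gave 0 (without WT animal 2, WT animal 3 or KO animal 10) to 2 that passed, and 2 to 4 that rose, while 2 fell without KO animal 11. These counts depend on which probe sets enter the gene value. That of Hddc3 (log2 1.20) is the mean of probe sets at log2 2.47 and -0.076. That of Iqgap1 (log2 -0.12) leaves out its passing probe set (log2 -1.83), which lay in a lower recovered band. Passing probe sets without a symbol of their own included 3 with log2 differences of -4.35, -4.07 and -3.59. At an adjusted p of 0.10, 14 of 30 named probe sets were on chromosome 7 (Fisher's exact p = 3.47e-09), that of Mfge8 among them.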
